A study of Mus musculus with 8 samples.

How the data were processed

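Total RNA of sorted CD8+ T cells was extracted with Qiagen RNeasy mini kits and treated with DNase, and biotinylated cRNA was made with the Illumina TotalPrep kit, per the labels' protocols. The cRNA was stained with Streptavidin-Cy3 and read in 1 colour on Illumina MouseRef-8 v2.0 arrays, per the labels. The submitters' processing notes name GenomeStudio, with no version, and no other settings are given in the sources used here. The authors deposited a table of non-normalized signal intensity per probe for the 8 arrays. Its intensity values are on a linear scale, differ in median between arrays and were used as deposited. Beside each intensity the deposited table gives a detection p-value, per the file headers, which falls as the signal of its array rises. The deposited series matrix holds processed log2 values whose steps are not stated. It was recomputed from the intensities to within 0.001 log2 on every array as log2 signals, quantile normalized and set relative to each probe's median over the arrays, with array medians between -0.00118 and 0.000611. These values therefore hold no background correction, run in the direction of the signals, and served as an alternative. The signal at which a probe saturates is not given in the sources used here, and the highest signal was 38472.2.

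Arrays were grouped by their labels into 4 CD8+YFP+ and 4 CD8+YFPneg samples. Intensities were corrected for background with the normexp model, its background estimated from the detection p-values, with an offset of 16, then quantile normalized and put on a log2 scale (neqc of limma 3.58.1 in R 4.3.3). An offset and quantile normalization compress the differences of dim probes, and quantile normalization removes any shift common to all probes. Probes were tested when their detection p was under 0.05 on at least 4 of the 8 arrays, a filter that does not look at the groups. This left 11183 probes and set aside 14514. Groups were compared with limma (lmFit and eBayes), two-sided, without covariates, and p-values were adjusted by the Benjamini-Hochberg method over the tested probes, with 0.05 as the threshold. A gene's probe with signal in 1 group and none above detection on any array of the other has a bound only. For these a lowest fold is given, the bright group's mean against, per dim array, the higher of the lowest detected signal and the probe's own.

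Probes were named from the platform annotation, which gives 1 symbol for 23978 probes and several for 0, while 1719 probes it does not list are unnamed here, not without a gene. Of the named probes, 23962 matched a current mouse gene table by Entrez identifier and 0 symbols needed an update. Genome coordinates were not used here. A gene was represented by its tested probe with the highest mean signal, which gave 7645 genes. Of 2047 genes with more than 1 tested probe, 0 had probes called in opposite directions, and 10 called genes had another tested probe of the opposite sign that did not pass.

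Designs, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the largest increase and the 12 with the largest decrease among genes past the threshold whose groups did not overlap. It further took fixed genes (among them Il17a, Il17f, Il22, Il23r, Ifng, Tbx21, Eomes, Gzmb, Prf1, Tnf, Csf2, Cd8a, Cd8b1, Cd4), and up to 4 members with the smallest adjusted p of each list that was called or discussed. Further list members named here were chosen after their values were seen. Of 25 fixed lists, 18 had at least 5 measured genes and were tested with camera of limma at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 18 lists. Camera was repeated with an estimated correlation. Fry, which tests a list's genes without comparing them with other genes, called 10 lists in 1 direction and 17 in either direction. Camera with the preset correlation called 5 lists (7 at an unadjusted p under 0.05), and 1 was called with an estimated correlation.

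The steps were tested on simulated signals with a known set of changed probes. For the comparison of YFP-positive and YFP-negative cells, run on 12753 probes, 41.8% of probes changed 1.5-fold, 79.1% of those changed 2-fold and 90.9% of those changed 4-fold were recovered, with 12 false calls among 153. A simulation with no change gave 0 calls. The gene list step was run on 12589 simulated probes, each taken as a gene. A list of 20 shifted by 0.5 log2 after normalization was called, and 0 of 17 unchanged lists were. The simulated noise was independent between probes, so this run cannot show false list calls that come from correlated genes.

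Alternatives covered scaling, background correction, offset, the deposited processed values, filters on dim probes, the variance prior, array weights, the replicate number, each array left out, a fold threshold, counting by genes, the probe rule and the estimated correlation. Leaving out YFP-positive replicates 1 and 3 together was added after seeing the data. No slide or scan batch is given in the sources used here.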

Results

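Gene expression was measured in CD8+ T cells of mice 7 days after an allogeneic transplant, sorted by a yellow fluorescent protein (YFP) and taken from liver, spleen and lymph nodes. In this study YFP marks T cells that have expressed interleukin 17A at some time, a reporter of cell history known from the study and not stated in the labels. Illumina MouseRef-8 v2.0 bead arrays, which read 1 fluorescent colour per array, were hybridised with 4 YFP-positive and 4 YFP-negative samples. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Each array reported 25697 probes, of which 11101 to 11433 (43.2% to 44.5%) were detected at a detection p under 0.05. Median signals ranged from 118 to 135.4 intensity units, and mean signals were 547 to 605 in YFP-positive samples and 495 to 554 in YFP-negative samples. Arrays of the same group correlated at 0.990 to 0.994 across probes and arrays of different groups at 0.984 to 0.989, a correlation across genes, which are not independent replicates. The first principal component held 36.8% of the variance and placed the YFP-positive arrays at 12.6 to 15.5 and the YFP-negative arrays at -11.7 to -15.2. The number of arrays, 4 per group, limits the precision of every difference below.

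The design implies 1 comparison: how CD8+ T cells with a history of interleukin 17A expression differ in transcripts from CD8+ T cells without one. YFP-positive cells had higher transcript levels of 10 of 17 measured type 17 genes, among them Ccr6, Ltb4r1 and Serpinb1a, and of the growth factor gene Csf2. Genes with lower levels included Eomes, Klrg1, Gzmk and the killer cell lectin-like receptor genes Klrh1, Klre1 and Klrk1. Of 11183 probes tested, 551 changed (limma, Benjamini-Hochberg adjusted p under 0.05), 322 of them higher and 229 lower in YFP-positive cells. Counted by each gene's brightest tested probe alone, 392 genes changed, 246 higher and 146 lower. At least a 2-fold difference was seen for 73 higher and 30 lower probes, and the groups did not overlap for 548 of the 551 probes. Groups did not overlap for 13.5% of all tested probes, against 2.86% given by chance with 4 arrays against 4. Median scaling in place of quantile normalization gave 1101 probes, 966 higher and 135 lower (87.7% against 58.4% higher), with the median of all probes shifted by 0.13 log2. The count also moved to 938 without background correction or from the submitters' processed values, to 965 with a trended robust variance prior, to 280 with a fold of at least 1.5, and to 253 with YFP-positive replicates 1 and 3 left out, a choice made after seeing the data.

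The gene with the largest increase was Tff1. It encodes a secreted trefoil peptide of mucosal surfaces and was 5.74-fold higher (95% interval 4.33 to 7.60), at 9.04 ± 0.14 log2 units in YFP-positive and 6.52 ± 0.41 in YFP-negative samples (SD, n = 4; limma adjusted p = 4.06e-05). Klrb1b, a lectin-like receptor of the CD161 family, was 5.49-fold higher (10.24 ± 0.08 against 7.79 ± 0.19; SD, n = 4; limma adjusted p = 5.40e-06), and its 3 other tested probes rose by 1.10 to 2.70 log2. Serpinb1a, an inhibitor of serine proteases, rose by 2.27 log2 (SE 0.16) and Igfbp7, which binds insulin-like growth factors, by 2.06 (SE 0.12). Il1r2, the decoy receptor for interleukin 1, rose by 2.01 log2 (SE 0.15) and Tnfrsf25, the receptor of the cytokine TL1A, by 1.98 (SE 0.19). Ccr6, the receptor of the chemokine CCL20, and Ltb4r1, the receptor of leukotriene B4, both rose by 1.91 log2 (SE 0.18 and 0.11). Tdrkh (1.89 log2), Epdr1 (1.78) and Csf2 (1.78), which encodes granulocyte-macrophage colony-stimulating factor, completed the set with Fcgr4. Fcgr4, a receptor for immunoglobulin G, rose by 2.00 log2 with a wider error (SE 0.35; limma adjusted p = 0.01004) and was detected on 2 of 4 YFP-negative arrays. Its values were 7.59 and 7.75 in YFP-positive replicates 1 and 3 and 5.88 and 6.72 in replicates 2 and 4. Of 35 changed probes unnamed in the annotation used, 18 were higher, led by ILMN_2760272 (2.93 log2, SE 0.14; detected on 2 of 4 YFP-negative arrays) and ILMN_1228245 (1.65, SE 0.14), and 17 lower, led by ILMN_2685393 (-1.22, SE 0.10) and ILMN_1215074 (-1.21, SE 0.13).

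The gene with the largest decrease was Klrh1. It encodes a killer cell lectin-like receptor and was 7.97-fold lower in YFP-positive cells (95% interval 5.82 to 10.9), at 5.54 ± 0.40 log2 units against 8.54 ± 0.28 (SD, n = 4; limma adjusted p = 3.58e-05). Il10ra, the ligand-binding chain of the interleukin 10 receptor, fell by 2.27 log2 (SE 0.11) and its ligand gene Il10, detected on 1 of 4 YFP-positive arrays, fell by 1.35 (SE 0.12). Eomes, a T-box transcription factor of effector and memory CD8+ T cells, was detected on all 4 YFP-negative arrays and not well above background on any YFP-positive array. It was at least 3.36-fold lower (limma adjusted p = 3.33e-05), a bound set by the lowest detected signal of each YFP-positive array. Klre1 fell by 2.11 log2 (SE 0.15) and Klrk1, which encodes the activating receptor NKG2D, fell by 1.70 (SE 0.11). Gzmk, the granzyme K gene, fell by 1.70 log2 (SE 0.15), from 13.26 ± 0.19 to 11.56 ± 0.30 (SD, n = 4). Klrg1, an inhibitory receptor of terminal effector T cells, fell by 1.45 log2 (SE 0.12). BC147527 (-1.64), Chn2 (-1.56; detected on 2 of 4 YFP-positive arrays), Mgst2 (-1.41) and Chchd10 (-1.34) were the remaining genes of this set, each with a limma adjusted p of 5.60e-04 or lower.

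**Figure D1:**
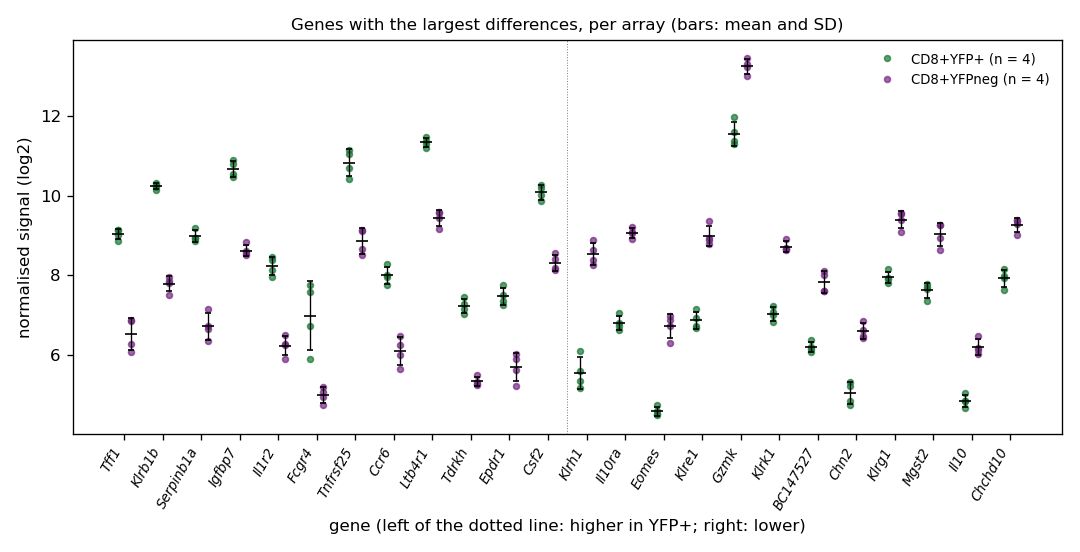
Normalised log2 signal per array for the 12 genes with the largest increases and the 12 with the largest decreases, in 4 CD8+YFP+ (green) and 4 CD8+YFPneg (purple) samples, with bars for mean and SD. The groups do not overlap for any of the 24 genes, and Fcgr4 has the widest spread in YFP-positive samples (SD 0.86).

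Several transcripts at the centre of the question were not different or not measurable. Il17a, the cytokine gene that defines the reporter, was detected on 3 of 4 YFP-positive and 1 of 4 YFP-negative arrays and was 4.99 ± 0.42 against 4.83 ± 0.23 log2 units (SD, n = 4; limma adjusted p = 0.716). The 95% interval of its difference ran from -0.28 to 0.61 log2. Probes for Il17f, Il22, Il23r, Gzmb and Cd8a were detected on 0 of 8 arrays and that for Cd4 on 2 of 8, so these genes were not tested. Since the cells were sorted as CD8+, the undetected Cd8a probe shows that a dim probe on this array does not mean an absent transcript. Ifng, the interferon gamma gene, was abundant and differed by -0.18 log2 (SE 0.13; limma adjusted p = 0.502). Tbx21, which encodes the type 1 regulator T-bet, differed by -0.06 (SE 0.10; adjusted p = 0.821). Median scaling turned its sign to 0.11, which is below the shift of 0.13 log2 of all probes under that scaling. Prf1, the perforin gene, differed by -0.30 (SE 0.14; adjusted p = 0.275) and Tnf by 0.15 (SE 0.07; adjusted p = 0.305). Cd8b1 differed by -0.04 (SE 0.07; adjusted p = 0.824) by its brightest probe, whereas its other tested probe gave -0.42 (adjusted p = 0.0170).

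Of 17 measured genes of the type 17 programme, 10 rose, 0 fell and 7 did not pass the test, and 13 rose when adjusted over the list alone. Next to Ltb4r1, Serpinb1a and Ccr6, the aquaporin gene Aqp3 rose by 1.69 log2 (SE 0.15) and Tmem176b by 1.44 (SE 0.14). Il1r1, Il17re and Tmem176a were not well above background on any YFP-negative array and were at least 1.56-fold, 1.55-fold and 1.41-fold higher. Rora, a nuclear receptor of type 17 cells, rose by 0.61 log2 (SE 0.10) and the interleukin 18 receptor gene Il18r1 by 0.40 (SE 0.09). Stat3 (-0.15), Irf4 (-0.07) and Batf (0.13), transcription factors of this programme, did not pass the test. The list's median difference was 0.61 log2, or 0.60 with the dim genes at their bounds, and its mean 0.83 (limma camera, adjusted p = 1.85e-12). This was the list of the 5 called that held with an estimated correlation (adjusted p = 0.0167 with an estimated correlation). Without background correction, which compresses dim genes, its median was 0.25 log2 and the call held.

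Of 20 measured type 1 effector genes, 0 rose, 6 fell and 14 did not pass, and 8 fell when adjusted over the list alone. Besides Eomes and Klrg1, the members that fell were the chemokine genes Ccl5 (-1.19 log2, SE 0.09), Ccl3 (-0.56, SE 0.10) and Ccl4 (-0.33, SE 0.08) and the surface marker Ly6c1 (-1.14, SE 0.13). The list's median was -0.31 log2 (limma camera, adjusted p = 1.72e-06, and adjusted p = 0.0668 with an estimated correlation). Of 17 cytotoxic granule genes, 0 rose, 4 fell and 13 did not pass, while 2 rose and 4 fell when adjusted over the list alone. The 4 were Gzmk, the lysosomal membrane gene Lamp1 (-0.76 log2, SE 0.10), the death ligand gene Fasl (-0.49, SE 0.09) and the granzyme M gene Gzmm (-0.90, SE 0.18). Gzmm lost its call without YFP-positive replicate 2 (adjusted p = 0.0509) or YFP-negative replicate 1 (0.0582), and Fasl without YFP-positive replicates 1 and 3 (0.115). The cytotoxic list did not pass (median -0.04 log2, camera adjusted p = 0.0994), and it passed under median scaling (0.0129), without background correction (0.0306), with an offset of 50 (0.0494) and with the submitters' processed values (0.0364).

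Natural killer cell receptor genes moved in both directions. Of 9 measured, 2 rose, 5 fell and 2 did not pass, with the same counts adjusted over the list alone. Klrb1b and Fcer1g, a signalling chain shared by Fc receptors, rose, the latter by 1.12 log2 (SE 0.16). Klre1, Klrk1, the inhibitory Ly49 receptor gene Klra7 (-1.33 log2, SE 0.30; detected on 1 of 4 YFP-positive arrays), Cd7 (-0.91, SE 0.13) and Klrd1 (-0.48, SE 0.09) fell. The list did not pass (median -0.48 log2, camera adjusted p = 0.0994), and it passed under median scaling (0.000731).

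**Figure D2:**
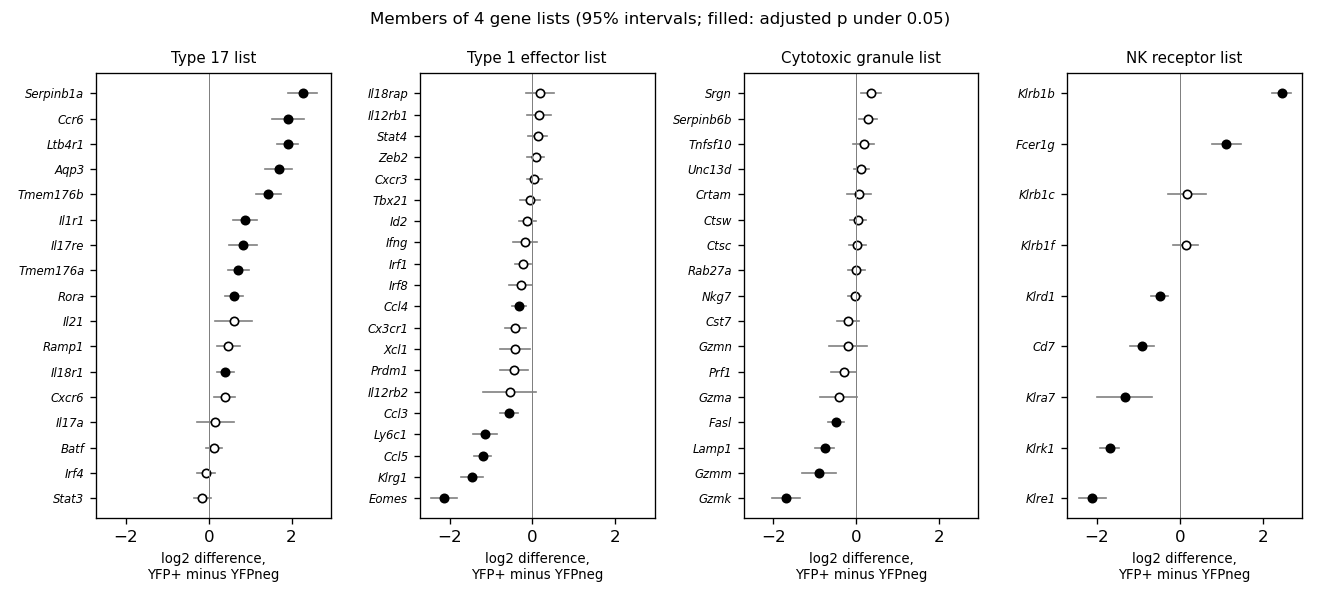
Log2 differences (CD8+YFP+ minus CD8+YFPneg, 4 samples each) of the measured members of the type 17, type 1 effector, cytotoxic granule and natural killer receptor lists, with 95% intervals as lines and filled points for a limma adjusted p under 0.05. The 10 filled points of the type 17 list lie right of 0, the 6 and 4 of the type 1 and cytotoxic lists left of it, and those of the natural killer receptor list on both sides.

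Among inflammatory cytokine genes, Csf2, Csf1 and Il18 rose and Il10 fell. Of 14 measured, 3 rose, 1 fell and 10 did not pass, with 4 higher and 1 lower adjusted over the list alone. Csf1, which encodes macrophage colony-stimulating factor, rose by 1.12 log2 (SE 0.12). Il18 was not well above background on any YFP-negative array and was at least 1.38-fold higher. The list's median was 0.17 log2 (camera adjusted p = 0.00684, and adjusted p = 0.296 with an estimated correlation). Its call ended without YFP-positive replicate 1 (adjusted p = 0.0885), without YFP-positive replicates 1 and 3 (0.0786) and with a stricter filter on dim probes (0.0520).

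Of 28 measured interferon-stimulated genes, 2 rose, 8 fell and 18 did not pass, with 2 higher and 10 lower adjusted over the list alone. The antiviral genes Oas1g (-0.58 log2, SE 0.08) and Ifit3 (-1.06, SE 0.23) fell, as did Usp18 (-0.96, SE 0.17) and Sp100 (-0.58, SE 0.09). In contrast, Oasl2, detected on 3 of 4 YFP-negative arrays, rose by 1.19 log2 (SE 0.14) and Ly6e by 0.48 (SE 0.09). The list's median was -0.20 log2 (camera adjusted p = 0.000202, and adjusted p = 0.289 with an estimated correlation). Usp18 and Sp100 lost their calls without YFP-positive replicates 1 and 3 (adjusted p = 0.0597 and 0.0608).

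Cell cycle genes had mostly negative differences. Of 32 measured, 0 rose and 0 fell by limma, over all probes or adjusted over the list alone, and 26 had a negative difference. The replication genes Mcm3 (-0.38 log2, SE 0.10; adjusted p = 0.0585) and Mcm5 (-0.29, SE 0.08; adjusted p = 0.0834) had the smallest p. The list's median was -0.10 log2 (camera adjusted p = 0.00239, and adjusted p = 0.289 with an estimated correlation). Under median scaling its median was 0.05 log2, below the shift of 0.13 log2 of all probes. Under that scaling the list was thus lower only relative to other genes. Single members fell in 6 alternatives: 4 without background correction, 2 with an offset of 50, 5 from the submitters' processed values, 6 with a trended robust variance prior, and 1 each with a stricter filter on dim probes and with the mean of a gene's probes.

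Activation genes included 4 that rose and 0 that fell among 19 measured, with 4 higher and 1 lower adjusted over the list alone. These were the costimulatory receptor genes Tnfrsf4 (0.87 log2, SE 0.09) and Icos (0.65, SE 0.11), the adhesion receptor gene Cd44 (0.57, SE 0.09; 0.30 and not called by its other tested probe) and the interleukin 2 receptor gene Il2ra (0.42, SE 0.09). The list's median was -0.07 log2 while its mean was 0.04 and its test pointed upward without passing (camera adjusted p = 0.702). Of 15 homing and adhesion genes, 3 rose (Emp1 by 0.56 log2, Cd9 by 0.47, and the oxysterol receptor gene Gpr183 by 0.56), 1 fell (Icam1 fell by 0.47) and 11 did not pass, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.151). Cd44, Icos, Il2ra, Cd9, Gpr183 and Icam1 lost their calls without YFP-positive replicates 1 and 3 (adjusted p = 0.0506 to 0.182), and Il2ra, Gpr183 and Icam1 also without single arrays of either group (0.0528 to 0.0790) and Icam1 under median scaling (0.136).

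The remaining lists were not called. Naive and memory genes (13 measured, median -0.24 log2, camera adjusted p = 0.291) and inhibitory receptor genes (12 measured, median -0.07, adjusted p = 0.324) had 0 members past the test in either direction. Adjusted over the list alone, 1 naive and memory gene was higher and 5 lower, and 3 inhibitory receptor genes were lower. T cell receptor complex genes (15 measured, adjusted p = 0.424) held 1 that rose, Lcp2 (0.44 log2), and 1 that fell, Fyn (-0.48), with 2 higher and 1 lower adjusted over the list alone. In the apoptosis list (15 measured, adjusted p = 0.518) the pro-apoptotic Bbc3 rose by 1.05 log2 and the death receptor gene Fas fell by 0.89. Glycolysis genes (17 measured, adjusted p = 0.797) held 1 that fell, Pgk1 (-0.96 log2; detected on 1 of 4 YFP-positive arrays), and the list's median was 0.01 against a mean of -0.05. Immediate-early and stress genes (15 measured, adjusted p = 0.750) held 1 that fell, Ddit3 (-0.63 log2), with a mean of 0.04 against a test that pointed downward. Oxidative phosphorylation genes (33 measured, median 0.02 log2, adjusted p = 0.424) and ribosomal protein genes (54 measured, median 0.04, adjusted p = 0.390) had 0 members past limma's test. Under median scaling, which shifted all probes by 0.13 log2, 5 oxidative phosphorylation genes (list median 0.19) and 1 ribosomal protein gene were higher, and other alternatives called at most 3 genes of either list. Adjusted over the list alone, the counts of the apoptosis, glycolysis, immediate-early, oxidative phosphorylation and ribosomal lists were the same as over all probes.

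Markers of other cells were measured beside these groups. The regulatory T cell factor gene Foxp3 rose by 0.61 log2 (SE 0.10; limma adjusted p = 0.00549), and its other tested probe gave 1.02. Cd163l1, a marker of gamma-delta T cells, rose by 1.16 log2 (SE 0.10; adjusted p = 0.000127). Of 4 endothelial and stromal markers 2 rose, Igfbp7 as given above and Pecam1, an adhesion molecule of endothelium and leukocytes, by 0.96 log2 (SE 0.13). The endothelial receptor gene Kdr (-0.13, adjusted p = 0.549) and Fcgr2b (0.18, adjusted p = 0.622) did not pass. Nor did Zbtb7b (0.55, adjusted p = 0.278), Tnfsf8 (0.48, adjusted p = 0.333) and Ikzf2 (-0.14, adjusted p = 0.774) of the list of Foxp3, or Slamf1 (0.33, adjusted p = 0.118) of that of Cd163l1. The globin gene Hba-a1, detected on 2 of 4 YFP-negative arrays, rose by 0.92 log2 (adjusted p = 0.0331), a call lost in 8 alternatives. Of 6 myeloid markers, 0 rose and 1, Itgax, detected on 1 of 4 YFP-positive arrays, fell by 0.76 log2 (SE 0.10), with a list median of 0.45 (camera adjusted p = 0.424). Adjusted over the list alone 1 was higher, Cst3 (0.38 log2, adjusted p = 0.0623 over all probes), and 1 lower. Lyz1 (1.03 log2, SE 0.48; adjusted p = 0.285), Cd74 (0.83, SE 0.44; adjusted p = 0.343) and H2-Ab1 (0.72, SE 0.37; adjusted p = 0.339) did not pass. Lyz1 was 7.30 and 7.25 log2 units in YFP-positive replicates 1 and 3 and 4.79 to 5.71 on the other 6 arrays. Without those 2 arrays the myeloid list's mean turned to -0.12 log2 relative to other genes and Cd74 to -0.055. Type 2, CD4 helper, gamma-delta, B cell, hepatocyte, erythroid and endothelial lists held 1 to 4 measured genes each and were not tested as lists. Within them Gata3 (0.12 log2, adjusted p = 0.661), Cd79b (0.37, adjusted p = 0.233; -0.06 by its other tested probe) and Apoa2 (0.40, adjusted p = 0.164) did not pass.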

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

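The covariate tests and the tests on Klrb1c and Il17a below were chosen only after their results were seen, while the count over splits was set beforehand. Of the 35 splits of the 8 arrays into 4 against 4, the real one alone reached its 551 probes (1 of 35, exact p = 0.0286). The highest other gave 1. Chance is thus unlikely for that count if the arrays are unpaired, but not excluded. If the replicate numbers pair the samples, fewer splits can be exchanged. The smallest exact p would then be larger, here and for the lists below. Every other split mixes the groups, so the group difference widens its spread and lowers its count. For the number of lists called, 5 with the real split, 5 splits reached it and the highest other gave 6, so chance cannot be excluded. The 4 other splits that reached it each held 3 arrays of 1 group and 1 of the other. List by list, the real split alone gave the largest mean difference for each of the 5 called lists (1 of 35 splits, exact p = 0.0286, Benjamini-Hochberg 0.0571), for type 17 genes 0.83 log2 against 0.51 in the largest other split. That is the smallest exact p that 35 splits can give, 4 lists not called reached it too, and the margin was narrow for interferon-stimulated genes (-0.2018 log2 against a size of 0.2001).

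The genes higher in YFP-positive cells were weighed against antigen-presenting cells. With the mean of Lyz1, H2-Ab1, Marco and Cd74 (all members of the fixed myeloid or B cell lists, at most 7.53 log2 units on any array) as a covariate, the 246 higher genes kept 99.98% of their median difference of 0.61 log2, all 246 kept their sign and 158 still passed; 8 type 17 genes passed, against 10 without it. The set thus did not follow these markers across the arrays. Since its genes were called against the spread within groups, where the markers varied most, this outcome was likely beforehand. It cannot exclude such cells as a source. All 4 markers had positive differences, so their mean is no neutral measure of such cells. The measured members of the same lists left out were Itgax (-0.76 log2), Cd22 (-0.09), S100a8 (0.11), Cd79b (0.37) and Cst3 (0.38). For Fcgr4, 68.3% of the difference stayed (2.00 to 1.37 log2; limma adjusted p = 0.0230), a loss of 1.80 standard errors of the fit without the covariate (SE 0.35) or 2.55 of the fit with it (SE 0.25), on either side of the limit of 2, so antigen-presenting cells and a difference in the T cells cannot be told apart for this gene with 4 arrays per group. A difference between cells with and without a history of Il17a expression remains a hypothesis, as do T cells of other kinds among YFP-positive cells, where Foxp3 and Cd163l1 were higher while Zbtb7b, Tnfsf8, Ikzf2 and Slamf1 did not pass, although all cells were sorted as CD8+ and Cd4 was detected on 1 array of each group.

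The lower natural killer receptor genes were weighed against natural killer cells among the YFP-negative samples. Such cells would bring their other transcripts, but Klrb1c, another of their receptor genes, differed by 0.18 log2 (95% interval -0.28 to 0.64) and Fcer1g was higher in YFP-positive cells (1.12, 0.77 to 1.47), both intervals above that of Klrk1 (-1.93 to -1.46). These 2 genes gave no sign of natural killer cells as the whole source, but they cannot decide it. Both were chosen after their values were seen, from the list's 4 members with a positive difference, while 5 of 9 members fell. Fcer1g is shared by Fc receptors and rose beside Fcgr4, so other cells may hide a decrease. Probes for Ncr1, Tyrobp and Fcgr3, further genes of the natural killer receptor list, were detected on too few arrays to be tested. A difference between the sorted CD8+ populations, named by the design, stays open and untested.

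Il17a did not differ between the groups although the reporter follows its expression. Its probe was detected on 4 of the 8 arrays, so a dim probe that hides a difference and similar current Il17a levels cannot be told apart. The 95% interval of the difference (-0.28 to 0.61 log2) excludes a larger increase on the compressed scale of a dim probe only.

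In 192 groups of 4 values examined, 5 held a value far from the others by Dixon's test, where 9.6 were due by chance. Il18 was 5.21 log2 units in YFP-positive replicate 2 and 5.51 to 5.54 in the others of its group. Zbtb7b was 6.19 log2 units in YFP-negative replicate 3 and 5.18 to 5.33 in the others. Itgax was 5.22 log2 units in YFP-positive replicate 1 and 4.93 to 4.97 in the others. The mean of the T cell receptor complex list was 11.88 log2 units in YFP-negative replicate 4 and 11.75 to 11.77 in the others. YFP-positive replicate 4 had 11101 detected probes, against 11368 to 11399 in the others.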

How the results depend on the processing

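The 24 genes of the largest changes kept direction and call in all 428 values computed for them under the alternatives. Of 1332 values of named genes, 1257 kept direction and side of the threshold, 36 lost the call, 28 gained it and 11 turned sign; of 359 list values these were 339, 7, 5 and 8. The probe count of 551 moved to 1101 under median scaling (452 shared), 938 without background correction and from the processed values (505 shared), 965 with a trended robust prior (517 shared), 280 with a fold of 1.5, which removes smaller changes by construction, and 253 (225 shared) with YFP-positive replicates 1 and 3 left out, an alternative chosen after seeing the data with fewer arrays. Other causes were not tested. Other alternatives gave 394 to 754, and leaving out 1 array gave 373 to 458, with 291 probes called in all of those fits and with all arrays. The list count of 5 fell to 1 with an estimated correlation and was 4 to 7 otherwise. Some values without a call turned sign, and the cause was not tested. Values of lists are relative to the median of all genes, those of single genes are not. Under median scaling ribosomal genes (-0.034) and Tbx21 turned sign (0.11, below the shift of 0.13 log2 of all probes). Immediate-early genes turned without background correction (-0.0097), and T cell receptor genes from the processed values (-0.0035). Apoe turned with an offset of 50 or array weights (-0.00076 and -0.017). Without YFP-positive replicates 1 and 3, immediate-early (-0.086) and myeloid genes (-0.12), Tbx21 (0.074) and Cd74 (-0.055) turned sign. Leaving out 1 array gave -0.040 to 0.10 for immediate-early genes, -0.10 to 0.036 for Tbx21, -0.13 to 0.085 for Apoe, -0.31 to 0.0084 for Ikzf2, -0.21 to 0.10 for Cd22 and -0.29 to 0.0063 for Hp. Residuals of same-numbered arrays correlated at 0.063 to 0.235, and those of other pairs at 0.033 at most. All 8 arrays correlated best with their own number, a hint from the data that the numbers pair the samples. The lowest value missed the rule set beforehand, so the main fit and the splits do not account for pairs. With the number as a replicate block 628 probes passed (481 shared), and no list call changed. A slide or scan batch as a block was not run. Signal over background limits genes such as Il17a.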

Other observations

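The gene families below were chosen after the data were seen, some because their members had changed, so their p-values describe these calls and are no independent test. They compare each family's share of changed genes with 5.13% of all genes (Fisher's exact test, one-sided, Benjamini-Hochberg over 22 families) and treat genes as independent. Matrix metalloproteinase and inhibitor genes held 3 of 5 that rose and 0 that fell (adjusted p = 0.00545). Mmp9 rose by 1.61 log2 (SE 0.10), Timp2, a secreted inhibitor of these proteases, by 1.04 (SE 0.10), and Mmp14, not well above background on any YFP-negative array, passed as well (adjusted p = 0.000793). Tetraspanin genes held 3 of 8 that rose, Tspan6 (0.96 log2), Tspan2 (0.92) and Tspan17 (0.57), and 1 that fell, Tspan3 (-0.63; family adjusted p = 0.00445). Of 8 S100 calcium-binding protein genes, 3 rose (S100a1 by 0.55 log2, S100a4 by 0.49, S100a10 by 0.36) and 0 fell (adjusted p = 0.0226). Relative to the median of all genes, the medians of these 3 families kept their positive sign under median scaling, without background correction and with an offset of 50.

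Of 22 interleukin receptor genes, 5 rose (Il1r2, Il1r1, Il17re, Il2ra, Il18r1) and 1, Il10ra, fell (adjusted p = 0.00474). Of 10 killer cell lectin-like receptor genes, 1 rose (Klrb1b) and 7 fell (adjusted p = 4.03e-08), Klra10 (-0.61 log2, SE 0.15; detected on 2 of 4 YFP-positive arrays) among those not named before. Of 10 chemokine genes, Ccl1 rose by 0.53 log2 (SE 0.13) while Ccl3, Ccl4 and Ccl5 fell (adjusted p = 0.00545), with 1 higher and 2 lower under median scaling. Of 4 granzyme genes, Gzmk and Gzmm fell and 0 rose (adjusted p = 0.0462). Proteasome (42), histone (55) and Trim (24) genes held 0 changed members by limma. Under median scaling 2 proteasome genes were higher and 1 Trim gene lower, and without background correction 3 proteasome genes were lower. Integrin genes outside the fixed lists, Itga3 (1.27 log2, SE 0.16) and Itgb5 (1.21, SE 0.09), rose, but the family as a whole did not pass (3 of 15 changed, adjusted p = 0.0846).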
